A study of Rattus norvegicus with 30 samples.

How the data were processed

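Each of the 30 arrays measured RNA from 1 well of rat hepatocytes, as biotin-labelled cRNA on a rat oligonucleotide array. The authors summarised the arrays with MAS5 (version not stated), and the deposited values are linear intensity values per probe set (signal), scaled on each array to a trimmed mean of 1500.0 between the 2nd and 98th percentiles. The table held 31099 probe sets, 57 of them controls. Median signals per array ran from 380 to 449, correlations between arrays of a group from 0.965 to 0.974 on average, and 3.86% of values lay below the floor used here. Samples were grouped by the dose and time given in the labels, with 5 arrays in each of 6 groups. Array numbers followed the same order of groups in every replicate, so position within a replicate cannot be told apart from dose and time.

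Signals were floored at 16 and log2 transformed with no further normalization. Probe sets were kept if they exceeded the 40th percentile of their own array on at least 5 arrays, which left 21226. Names came from the platform annotation and were checked by Entrez identifier against a current gene table: 20826 probe sets had 1 symbol, 436 had several and 9780 were not listed. A gene was represented by its kept probe set with the highest mean over the arrays, which gave 11503 genes. A gene is called dim in a comparison where the lower of its 2 group means lay below the log2 of the mean 40th percentile of the arrays. Genes are described at the level of transcripts, and protein was not measured.

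Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 30 arrays, eBayes with a trend and Benjamini-Hochberg adjustment over all genes within each comparison. A gene changed where the adjusted p was under 0.05, and the word is used in that sense. Comparisons were each dose against vehicle at each time, 20 against 0.8 µM, the difference of the 20 µM effects between the times, and vehicle at 48 against 24 h. The 36 lists were tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a comparison. An exact permutation of the mean of each list per array was added after the data had been seen, and its smallest p is 0.00794.

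The gene lists, the fixed panel of 24 genes (4 of them not analysed here), the tests and the rule for naming genes were set before the data were examined. The rule names the 10 largest rises and falls at 20 µM against vehicle, and 5 of each in other comparisons, among changed genes whose arrays do not overlap. For the difference of the 20 µM effects between the times, overlap of arrays was not considered. It also names up to 4 changed members of each list with the largest change, and the panel. Genes known by a locus number were counted and not named. Agreement between comparisons that share vehicle arrays was set beside 100 simulated sets of unchanged groups and beside 20 splits of the vehicle arrays.

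The procedure was tested on simulated data with 11635 genes and 50 genes at each of 4 sizes: 15 of those changed 1.25-fold, 32 of those changed 1.5-fold, 41 of those changed 2-fold and 47 of those changed 4-fold were called. A list of 29 genes shifted by 0.5 was simulated beside them, and of all 166 calls 7 were of genes with no simulated change (4.22%). Each probe set was drawn independently, so the simulated arrays lack correlation between genes. The share of false calls on the real arrays may therefore differ. Alternatives covered the floor, the filter, normalization, the spread model, array weights, the arrays in the fit, the order of the arrays, the summary of probe sets, the threshold, the list test and leaving out each array. Probe sets without a single gene name were left out of the comparisons, as a name is needed to place them in a list. Positions in the genome were not used.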

Results

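Expression was measured in cultured primary hepatocytes, the main metabolic cell type of the liver, from male Sprague Dawley rats. On day 3 of culture the cells received chlorpromazine hydrochloride, a phenothiazine antipsychotic drug known for cholestatic liver injury, at 0.8 or 20 µM, or only the vehicle dimethyl sulfoxide at 1%. The titles of the treated samples give no content of dimethyl sulfoxide. RNA was taken 24 or 48 h later from 5 wells for each of the 6 combinations, and each well had its own array, which gave 30 arrays. The labels call the wells independent cultures and name no separate animals, so the p-values measure the spread between cultures. The study asked how the transcripts of these cells respond to dose and time. The title of vehicle replicate 2 at 24 h gives 2 h and its time entry gives 24 h, and it was grouped by the time entry. Its mean correlation with the other arrays of that group was 0.969, within the range of 0.965 to 0.969 in the group. With no 2 h group to compare, this does not decide between the 2 entries.

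After a filter on dim signals, 11503 named genes were tested. Values are log2 changes ± SE with 5 arrays per group unless stated otherwise, and the number of arrays limits their precision. The first principal component held 16.04% of the variance, and the 10 arrays at 20 µM lay between 14.7 and 30.5 on it, above the other 20 arrays (-21.4 to -1.40). The second component held 8.46% and placed the 48 h arrays between 8.35 and 15.4, above all 24 h arrays (-19.1 to -0.285).

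**Figure D1:**
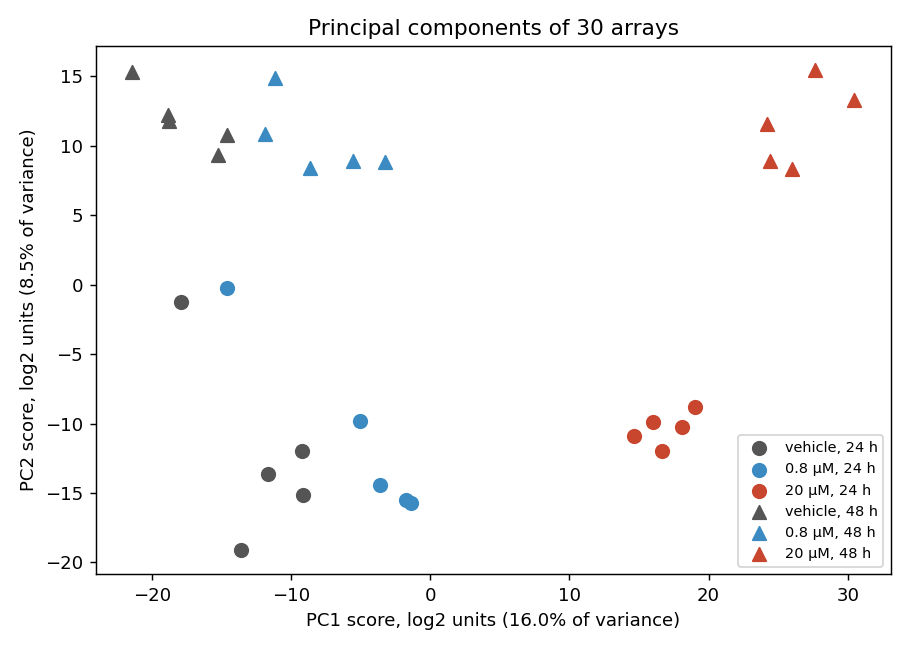
Scores of the 30 arrays on the first and second principal components of the log2 signals of the tested genes (both axes in log2 units). Points are single arrays, coloured by dose and shaped by time, and the 20 µM arrays stand at 14.7 to 30.5 on the horizontal axis.

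At 20 µM and 24 h, hepatocyte genes for bile acid synthesis, amino acid breakdown, glucose production and fatty acid oxidation fell, and targets of the transcription factors NRF2 and p53 and genes of cholesterol synthesis rose. Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, fell 3.51-fold, from a mean log2 signal of 13.79 ± 0.11 to 11.98 ± 0.21 (SD, n = 5, adjusted p = 2.39e-15). Nqo1, a quinone reductase, rose 2.05-fold, from 14.75 ± 0.07 to 15.78 ± 0.09 (SD, n = 5, adjusted p = 2.39e-15). Of the tested genes, 2738 changed (23.8%), 1537 of them higher and 1201 lower, and with the arrays centred on their medians 1849 were higher and 828 lower. A change of at least 2-fold was found for 109 genes, 39 higher and 70 lower. The arrays of both groups did not overlap for 16.8% of all tested genes, against 0.794% by chance.

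The largest rises at 24 h included Ampd3, an AMP deaminase (1.60 ± 0.12), Rragd, a GTPase of the lysosomal amino acid sensing machinery (1.54 ± 0.12), Tsx (1.57 ± 0.18) and Prcp, a lysosomal carboxypeptidase (1.52 ± 0.42). Snap91 (2.32 ± 0.44), Scamp5 (2.06 ± 0.49), Hcrt (1.92 ± 0.55), Uchl1 (1.72 ± 0.58), Pla2g4b (1.61 ± 0.51) and Zmat5 (1.45 ± 0.40) also rose but were dim. The largest falls included Bbox1, which makes carnitine (-2.00 ± 0.14), Acsm3, a medium-chain acyl-CoA synthetase (-1.84 ± 0.17), AKR1C3l1 (-1.60 ± 0.19) and Klkb1, plasma prekallikrein (-1.52 ± 0.13). The dim genes Sult2a6 (-1.92 ± 0.20), Pfkfb4 (-1.85 ± 0.49), Pth2r (-1.66 ± 0.58), Slc13a4 (-1.66 ± 0.45) and Cyp17a1 (-1.55 ± 0.17) fell as well. Leaving out single arrays ended the calls of Uchl1 (4 of 10 arrays), Pla2g4b (2 of 10) and Pth2r (7 of 10), and without replicate 5 of 20 µM the change of Pfkfb4 was -1.22.

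At 20 µM and 48 h, the loss of P450, transporter and fatty acid oxidation transcripts was larger, and lysosomal genes rose. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 6.81-fold, from a mean log2 signal of 11.76 ± 0.27 to 8.99 ± 0.33 (SD, n = 5, adjusted p = 8.06e-11). Slc10a1, the sodium-dependent bile acid importer of the basolateral membrane, fell 5.62-fold from a mean of 13.49 ± 0.13 (SD, n = 5; log2 change -2.49 ± 0.11, adjusted p = 3.03e-17). Ddit3, the stress transcription factor CHOP, rose 2.46-fold, from 11.51 ± 0.16 to 12.80 ± 0.15 (SD, n = 5, adjusted p = 1.55e-10). Alb, which codes for albumin, was at 16.56 ± 0.16 in vehicle and 16.49 ± 0.23 at 20 µM (SD, n = 5, adjusted p = 0.73). In all 4050 genes changed (35.2%), 2338 higher and 1712 lower, and 373 of them changed at least 2-fold, 137 higher and 236 lower. The arrays of both groups did not overlap for 25.9% of all tested genes, against 0.794% by chance.

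Among the largest rises at 48 h were Eno2, the neuronal form of the glycolytic enzyme enolase (2.69 ± 0.17), Sfn, 14-3-3 sigma (2.48 ± 0.11), Il1r2, the decoy receptor of interleukin-1 (2.22 ± 0.13), Rragd (2.02 ± 0.12), Zdhhc18 (1.99 ± 0.22) and Gpnmb, a transmembrane glycoprotein of lysosomes and melanosomes (1.96 ± 0.10). The dim genes Lama5 (2.83 ± 0.54), Dsel (2.39 ± 0.46), Coro1a (2.35 ± 0.62) and 2810025M15Rikl (2.34 ± 0.57) rose too. The largest falls were of Ces1d, a carboxylesterase (-3.41 ± 0.16), Akr1c1 (-3.01 ± 0.14), Cyp4a1, a fatty acid omega-hydroxylase (-2.93 ± 0.15), Otc, the urea cycle enzyme ornithine transcarbamylase (-2.82 ± 0.25), Cyp7a1 (-2.77 ± 0.25) and Bbox1 (-2.75 ± 0.14). The dim genes Sult2a6 (-3.58 ± 0.20), Olr59 (-3.05 ± 0.36), Dhrs7l1 (-2.96 ± 0.14) and Cyp2c12 (-2.77 ± 0.41, and -2.08 without replicate 4 of 20 µM) fell with them.

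**Figure D2:**
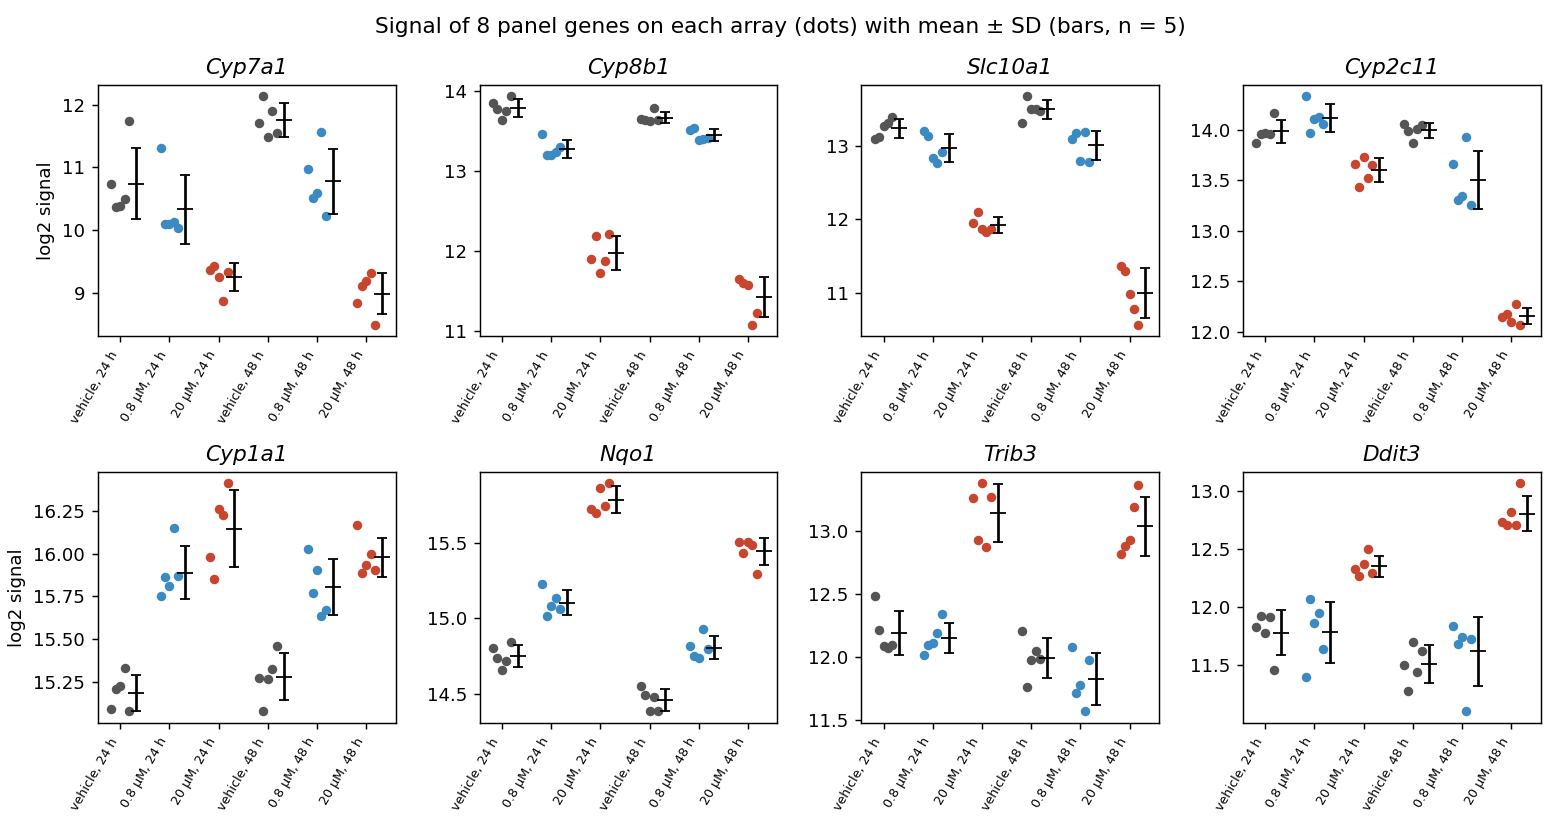
Log2 signal of 8 genes on each array (dots) beside the mean ± SD of each group (bars, n = 5), with dose and time on the horizontal axis. Cyp7a1 fell from a mean of 11.76 to 8.99 at 20 µM and 48 h.

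Genes were also described by 36 lists fixed in advance, some of which share members. With its preset correlation, limma's camera test, which asks whether a list moved more than the other genes, called 22 lists at 20 µM and 24 h (10 higher, 12 lower) and 20 at 48 h (9 higher, 11 lower). Over other splits of the same arrays that test called a median of 9 lists at each time and at most 22 and 23, and 4 and 13 of 100 splits, the real one included, gave as many as the real one. Each other split keeps part of any real difference, as 5 arrays cannot be divided evenly, so these counts are not a rate by chance. With an estimated correlation, 13 held at 24 h and 10 at 48 h. Those that held at both times were the targets of the aryl hydrocarbon receptor (AhR) and of p53, which rose, and 7 lists that fell: constitutive P450 and flavin monooxygenase enzymes, amino acid catabolism, gluconeogenesis, bile acid synthesis, fatty acid oxidation, transporters, and cholesterol efflux. Targets of NRF2, aminoacyl-tRNA synthetases, cholesterol synthesis enzymes and the proteasome held at 24 h alone, and lysosomal proteins at 48 h alone, though the difference between the times was tested separately and is given further on.

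**Figure D3:**
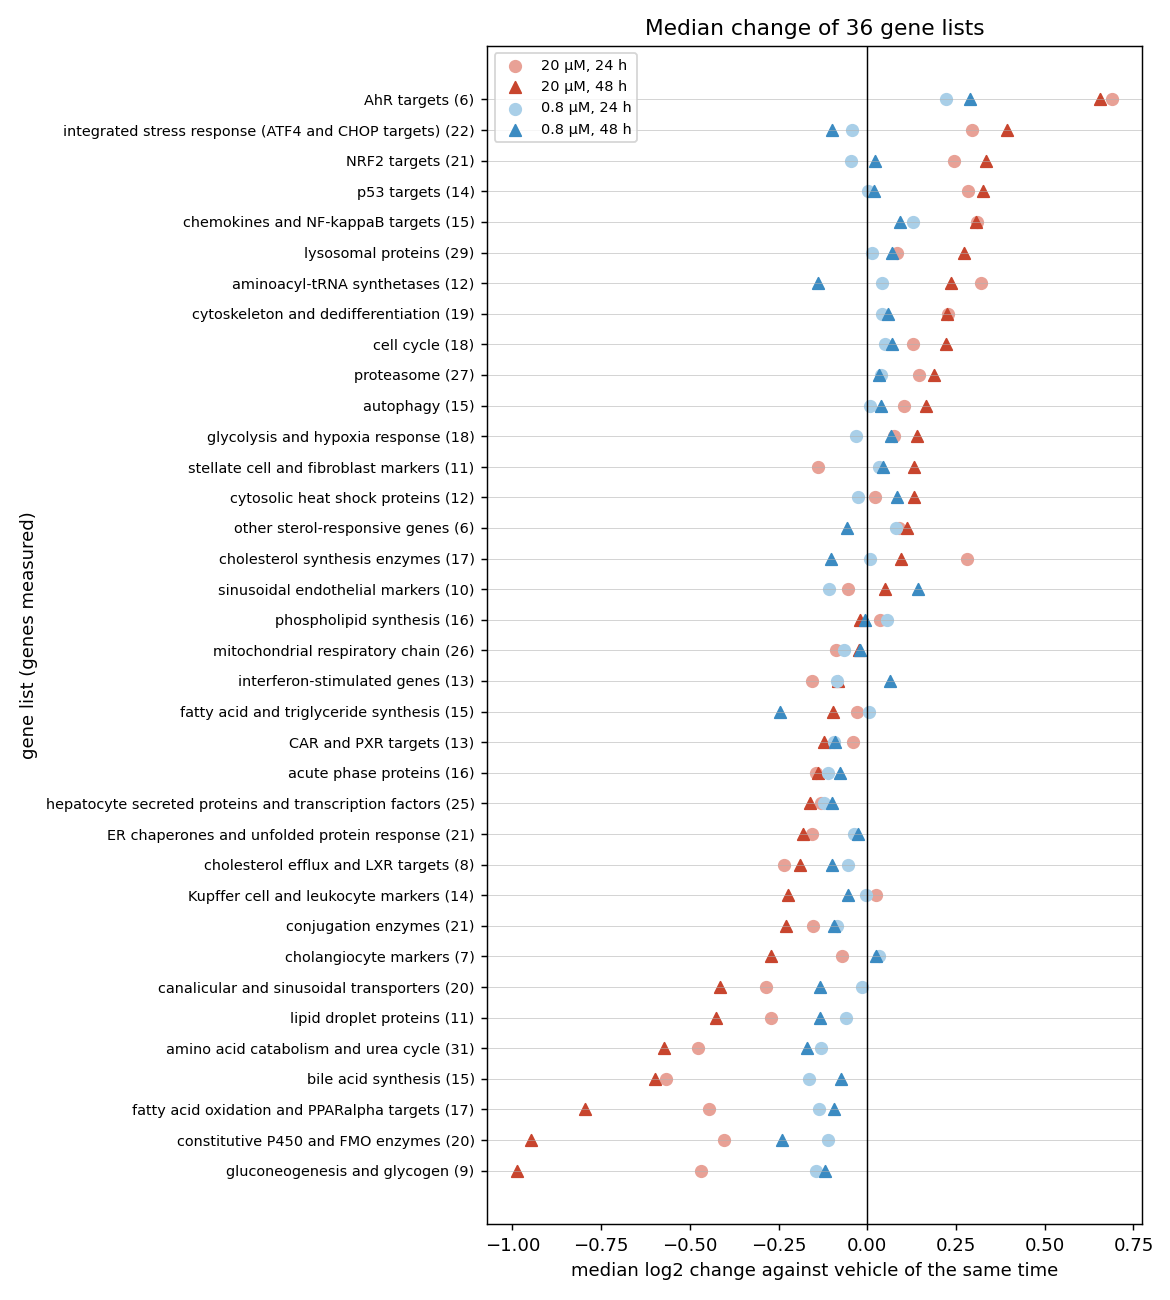
Median log2 change against vehicle of the same time for the measured genes of each list (number in parentheses), for both doses and times. The horizontal axis is in log2 units, and at 20 µM and 48 h the medians ran from -0.99 for gluconeogenesis and glycogen to 0.66 for AhR targets.

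P450 enzymes, bile acid synthesis genes and transporters fell at 20 µM, and in this and the following paragraphs counts in parentheses are those adjusted over the list alone. Of 20 constitutive P450 and flavin monooxygenase genes, 14 fell at 24 h (15) and 16 at 48 h (17), and 0 rose (adjusted p = 0.00154 and 0.000107 with an estimated correlation). At 24 and 48 h Cyp2e1 (-0.70 and -2.48), Cyp2a2 (-0.77 and -1.92) and the male-specific Cyp2c11 (-0.38 and -1.84) fell. Of 15 bile acid synthesis genes, 12 fell at each time (12 and 12) and 0 rose (adjusted p = 0.0174 and 0.0121 with an estimated correlation). Cyp7a1 (-1.495 and -2.77), Cyp8b1 (-1.81 and -2.24) and Slc27a5, the bile acid CoA ligase (-0.93 and -1.99), fell. Of 20 canalicular and sinusoidal transporters, 9 fell and 2 rose at 24 h (10 and 3), and 12 fell and 2 rose at 48 h (13 and 3), with adjusted p = 0.0164 and 0.000555 with an estimated correlation. The uptake transporters Slc10a1 (-1.31 and -2.49) and Slco1a4 (-0.90 and -1.84) fell, as did the bile salt export pump Abcb11 (-0.33 and -0.47) and the phospholipid translocator Abcb4 (-0.46 and -0.86). Abcc2, which exports conjugates (0.55 and 0.46), and Abcb1a, a drug efflux pump (0.79 and 0.87), rose.

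Of 21 conjugation enzymes, 5 fell and 1 rose at 24 h (7 and 1), and 12 fell and 2 rose at 48 h (13 and 2), with Sult1e1, an estrogen sulfotransferase, at -2.33 ± 0.16 at 48 h. That list's call was lost at both times (adjusted p = 0.153 and 0.125 with an estimated correlation). Targets of the nuclear receptors CAR and PXR went both ways, with 4 of 13 higher and 2 lower at 24 h (4 and 2) and 2 higher and 4 lower at 48 h (2 and 5). Their list did not pass the test (camera adjusted p = 0.771 and 0.12), and at 24 h its median lay below 0 and its mean and test above. In that list Cyp3a18 (-0.79 and -2.13) and, at 48 h, Cyp3a9 (-0.59) fell, while Cyp3a9 at 24 h was at -0.13 ± 0.15 (adjusted p = 0.609). Of 6 measured AhR targets, 5 rose at 24 h (5) and 4 at 48 h (4) and 0 fell (adjusted p = 0.00122 and 0.00567 with an estimated correlation). Nqo1 is in this list and also in that of NRF2 targets. Cyp1a1 rose by 0.96 and 0.70, Cyp1a2 by 0.54 and 1.07, and Tiparp by 0.61 at 48 h.

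Amino acid catabolism, gluconeogenesis and fatty acid oxidation fell with the P450 genes. Of 31 genes of amino acid catabolism and the urea cycle, 21 fell at 24 h (24) and 23 at 48 h (27), 1 rose at 48 h (1), and the list fell (adjusted p = 0.00258 and 0.00277 with an estimated correlation). Bhmt, a homocysteine methyltransferase, fell (-1.19 and -1.65), and so did Otc at 48 h (-2.82). Of 9 genes of gluconeogenesis and glycogen, 5 fell at 24 h (6) and 7 at 48 h (8), and 0 rose (adjusted p = 0.00337 and 0.00277 with an estimated correlation). Pc, pyruvate carboxylase (-1.08 and -1.60), and Gys2, the liver glycogen synthase (-0.94 and -1.23), fell. Of 17 genes of fatty acid oxidation and PPARalpha targets, 12 fell at 24 h (14) and 16 at 48 h (16), and 0 rose (adjusted p = 0.0174 and 0.00567 with an estimated correlation). Angptl4 (-0.97 and -2.03) and Pdk4, a kinase that restrains pyruvate oxidation (-0.51 and -1.48), fell. The other kept probe set of Pdk4 was not called at either time. Of 26 respiratory chain genes, 9 fell at 24 h (9), and 5 fell and 2 rose at 48 h (2 and 2), all by less than 0.32. The list was called lower at 24 h, but not with an estimated correlation (adjusted p = 0.302 with an estimated correlation), and not at 48 h (camera adjusted p = 0.467). Of 18 genes of glycolysis and the hypoxia response, 4 rose and 1 fell at 24 h (4 and 1; camera adjusted p = 0.504). At 48 h 9 rose and 0 fell (9), among them the lactate exporter Slc16a3 (1.22 ± 0.16) and the glucose carrier Slc2a1 (1.10 ± 0.15), and that call was lost (adjusted p = 0.299 with an estimated correlation).

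Lipid and sterol genes split. Of 17 cholesterol synthesis enzymes, 9 rose and 1 fell at 24 h (10 and 2; adjusted p = 0.0395 with an estimated correlation), led by Cyp51 (1.00 ± 0.09), Acat2 (0.74 ± 0.07) and Idi1 (0.57 ± 0.08). At 48 h 8 rose and 4 fell (8 and 4), with Cyp51 at 0.73 ± 0.09 and Dhcr7 at -0.77 ± 0.14, and the list did not pass (camera adjusted p = 0.404). Of 6 other sterol-responsive genes, Npc2, a lysosomal cholesterol carrier, rose by 0.31 and 0.91 and Insig1 by 0.27 and 0.26, and 1 gene, Tmem97, fell at 48 h (-0.33) (2 higher at 24 h, 2 higher and 1 lower at 48 h). Their list did not pass (camera adjusted p = 0.079 and 0.267). Of 8 genes of cholesterol efflux and LXR targets, 3 fell at 24 h (3) and 4 at 48 h (4), with 0 higher, and Abcg1 fell (-0.73 and -1.07; adjusted p = 0.0395 and 0.0426 with an estimated correlation). Fatty acid and triglyceride synthesis went both ways: of 15 genes, 5 rose and 4 fell at 24 h (5 and 5), and 3 rose and 6 fell at 48 h (3 and 6). Fads1, a fatty acid desaturase, rose by 0.98 and 1.35, Acaca, acetyl-CoA carboxylase, fell (-0.92 and -1.17), and Fasn fell at 48 h (-0.76) after -0.33 ± 0.14 at 24 h (adjusted p = 0.105). The other kept probe set of Fasn was called lower at both times when all kept probe sets were tested. The list of fatty acid and triglyceride synthesis did not pass (camera adjusted p = 0.572 and 0.0764), and its mean at 24 h lay above 0 while its median and test lay below. Of 11 lipid droplet proteins, 5 fell and 1 rose at 24 h (6 and 1) and 7 fell and 1 rose at 48 h (8 and 1), and the call was lost (adjusted p = 0.155 and 0.0846 with an estimated correlation). Phospholipid synthesis showed 2 of 16 genes higher and 1 lower at 24 h (2 and 1), and 3 higher and 4 lower at 48 h (3 and 4), with Pemt, which makes phosphatidylcholine, lower (-0.84 and -1.58). Its list did not pass (camera adjusted p = 0.771 and 0.331).

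Lysosomal transcripts rose at 48 h. Of 29 lysosomal genes, 9 rose and 2 fell at 24 h (9 and 2; adjusted p = 0.201 with an estimated correlation), and 20 rose and 2 fell at 48 h (21 and 3; adjusted p = 0.026 with an estimated correlation). Examples were the proton pump subunits Atp6v1h (0.44 and 0.63) and Atp6ap1 (0.71 at 48 h) and the protease Tpp1 (0.59 at 48 h). Autophagy genes showed 4 of 15 higher at 24 h (4) and 6 at 48 h (6, with 1 lower), Sqstm1 rising by 0.25 and 0.26, and the list did not pass (camera adjusted p = 0.126 and 0.0736). Of 27 proteasome genes, 14 rose at each time (15 and 14) and 0 fell, each by less than 0.40, for example Psma5 (0.34 and 0.38). The call held at 24 h and was lost at 48 h (adjusted p = 0.0343 and 0.0846 with an estimated correlation).

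Lists of stress responses went different ways. Of 22 targets of the integrated stress response, in which ATF4 and CHOP act, 14 rose and 2 fell at 24 h (15 and 2) and 15 rose and 2 fell at 48 h (16 and 2). Trib3 rose by 0.95 and 1.04, Asns, asparagine synthetase, by 0.79 and 0.59, and Ddit3 by 0.57 and 1.30. The list call was lost at both times (adjusted p = 0.0707 and 0.0998 with an estimated correlation). Of 12 aminoacyl-tRNA synthetases, 10 rose at 24 h (11) and 7 at 48 h (8) and 0 fell, with Sars1 at 0.65 and 0.92 (adjusted p = 0.0164 and 0.12 with an estimated correlation). Of 21 NRF2 targets, 11 rose and 1 fell at 24 h (12 and 1), and 11 rose and 3 fell at 48 h (12 and 4), with adjusted p = 0.0156 and 0.0998 with an estimated correlation. Besides Nqo1 (1.03 and 0.99), Gpx2 rose by 0.60 and 0.68 and Srxn1 by 0.68 at 48 h, and Hmox1 rose by 0.38 at 48 h after 0.17 ± 0.08 at 24 h (adjusted p = 0.142). Of 14 p53 targets, 7 rose and 1 fell at each time (7 and 1, 8 and 1; adjusted p = 0.0049 and 0.00567 with an estimated correlation), with Aen (0.70 and 0.88) and Ccng1 (0.56 and 0.80) higher and Sesn1 (-0.58 and -0.80) lower. The p53 target Cdkn1a was at -0.10 ± 0.09 and 0.02 ± 0.09 (adjusted p = 0.496 and 0.896). Endoplasmic reticulum chaperones went down more than up: 7 of 21 fell and 2 rose at 24 h (13 and 2), and 10 fell and 2 rose at 48 h (10 and 2), with Hsp90b1 lower (-0.34 and -0.48). Their call was lost (adjusted p = 0.138 and 0.116 with an estimated correlation), and the chaperone Hspa5 was at -0.11 ± 0.04 and -0.07 ± 0.04 (adjusted p = 0.063 and 0.194). Of 12 cytosolic heat shock genes, 3 rose and 2 fell at 24 h (4 and 2) and 5 rose and 3 fell at 48 h (6 and 4; camera adjusted p = 0.802 and 0.795), with Hsph1 higher (0.29 and 0.57, the call at 24 h lost without 4 of 10 single arrays) and Hspa1a lower (-0.81 and -0.62), and at 24 h the mean lay below 0 and the median and test above.

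Some genes of cell shape and of the differentiated state changed as well. Of 19 cytoskeleton and dedifferentiation genes, 10 rose and 1 fell at 24 h (10 and 1), and 10 rose and 2 fell at 48 h (11 and 3), among them Anxa5 (0.97 and 1.15), Lgals3 (0.69 and 0.87) and Tubb5 (1.03 at 48 h). That call was lost (adjusted p = 0.146 and 0.173 with an estimated correlation). Of 25 hepatocyte secreted proteins and transcription factors, 9 fell at 24 h (9) and 10 at 48 h (11), and 0 rose, with the factors Foxa1 (-0.85 and -1.39), Cebpa (-0.77 and -1.13) and Nr1i3 (-0.73 and -1.20) lower. That call was lost too (adjusted p = 0.153 and 0.136 with an estimated correlation). Of 18 cell cycle genes, 2 rose and 1 fell at 24 h (2 and 1), and 7 rose at 48 h (7), among them Tyms, thymidylate synthase (0.58 and 0.88), and the dim genes Ccne1, Mcm6 and Aurka at 48 h, whose calls were lost without 6, 6 and 4 of 10 single arrays (camera adjusted p = 0.433 and 0.12). Of 15 chemokine and NF-kappaB genes, 4 rose at 24 h (4; adjusted p = 0.0826 with an estimated correlation), among them Cxcl1 (0.70 ± 0.13), and 5 at 48 h (5; camera adjusted p = 0.181). Of 16 acute phase genes, 1 rose and 4 fell at 24 h (1 and 4), and 2 rose and 5 fell at 48 h (2 and 6; camera adjusted p = 0.132 and 0.12), with Hamp, the iron hormone hepcidin, higher by 1.92 ± 0.25 at 48 h, where the mean lay above 0 and the median and test below. Of 13 interferon-stimulated genes, 1 rose and 3 fell at 24 h (1 and 3) and 4 rose and 2 fell at 48 h (4 and 3; camera adjusted p = 0.332 and 0.685), and at 48 h the mean lay above 0 and the median and test below.

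Markers of other liver cell types were measured beside these groups. Over 42 markers of 4 types, the median was -0.07 ± 0.05 at 24 h (0 higher, 4 lower) and -0.04 ± 0.09 at 48 h (2 higher, 6 lower), and 38 of the 42 had a mean below the median of all values of the tested genes. The SEs of these medians come from resampling the 42 genes, which are not independent replicates, and do not measure the spread between arrays. Of 14 Kupffer cell and leukocyte markers, 1 fell at 24 h (1), and 1 rose and 3 fell at 48 h (1 and 3; camera adjusted p = 0.607 and 0.189), with the lysosomal glycoprotein Cd68 higher by 1.44 ± 0.13 and Lyz2 lower (-0.79) at 48 h. Of 11 stellate cell markers 1 fell at each time, Rgs5 (1 and 1; camera adjusted p = 0.332 and 0.795). Of 10 sinusoidal endothelial markers 1 fell at 24 h, Eng, and 0 at 48 h (0 and 0; camera adjusted p = 0.567 and 0.927). Of 7 cholangiocyte markers 1 fell at 24 h (1), and 1 rose and 2 fell at 48 h (1 and 2; camera adjusted p = 0.567 and 0.476). The calls of Rgs5 and Eng at 24 h were lost without 3 and 5 of 10 single arrays. The median and the test differed in sign for the Kupffer list at 24 h and for the stellate and endothelial lists at 48 h.

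Effects at 20 µM ran alike at both times. Across genes, which are not independent replicates, the log2 changes at 24 and 48 h correlated with r = 0.596. Both times shared 1170 higher genes (312 from independent lists) and 956 lower genes (179 from independent lists), and 9 genes changed in opposite directions. The 2 comparisons used different arrays.

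At 0.8 µM and 24 h, few genes changed, and AhR targets were among those that rose. Cyp1a1, a P450 induced through that receptor, rose 1.63-fold, from a mean log2 signal of 15.19 ± 0.10 to 15.89 ± 0.15 (SD, n = 5, adjusted p = 5.47e-05). Cyp8b1 fell 1.43-fold (-0.51 ± 0.09, adjusted p = 0.00489). In all 95 genes changed (0.826%), 46 higher and 49 lower, and 4 of them changed at least 2-fold. Of the largest rises among named genes whose arrays did not overlap, Cyp1a1 (0.70 ± 0.09) and Hmgn3 (0.45 ± 0.05) stood beside Tipin (0.70 ± 0.18), Sema3c (0.57 ± 0.13) and Asb3 (0.47 ± 0.11). The largest falls among such genes were Nuak2 (-0.96 ± 0.19), RT1-Db1 (-0.73 ± 0.17), Cyp8b1, Ces1e (-0.48 ± 0.12) and Cyp2d3 (-0.47 ± 0.08). Leaving out single arrays ended the calls of Tipin and Sema3c (7 of 10 arrays each), Asb3 (8), Nuak2 (3), RT1-Db1 (6) and Ces1e (9), and those of Cyp1a1, Hmgn3, Cyp8b1 and Cyp2d3 held without each of the 10. Of the panel, Hspa5 (-0.18 ± 0.04, adjusted p = 0.0317) and Abcb11 (-0.18 ± 0.04, adjusted p = 0.0319) also fell, and their calls were lost without 7 and 6 of 10 single arrays. Of 6 AhR targets 3 rose (3 adjusted over the list alone), Cyp1a1, Nqo1 (0.35 ± 0.05) and Cyp1a2 (0.33 ± 0.07), with adjusted p = 0.00144 with an estimated correlation, and the call of Cyp1a2 was lost without replicate 4 of vehicle or replicate 5 of that dose. Of 31 amino acid catabolism genes 3 fell (7 adjusted over the list alone), of 20 P450 and flavin monooxygenase genes 2 (6), and of 9 gluconeogenesis genes 1 (3), each list with adjusted p = 0.0422 with an estimated correlation. Another 8 lists were called lower by the preset test and lost their call, among them bile acid synthesis (adjusted p = 0.138 with an estimated correlation) and fatty acid oxidation (adjusted p = 0.191 with an estimated correlation). The count was not stable: leaving out single arrays moved it between 16 and 147, fitting the compared groups alone gave 7 genes, and the exact permutation test of list means called 0 lists, its smallest adjusted p being 0.143.

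At 0.8 µM and 48 h, AhR targets stayed higher than vehicle and genes of fatty acid synthesis, P450 enzymes and transporters were lower. Cyp1a2 rose by 0.77 ± 0.07 (adjusted p = 3.04e-08), and Sult1e1, an estrogen sulfotransferase, fell (-1.36 ± 0.16, adjusted p = 2.71e-06). Acaca (-0.66 ± 0.09) and Slco1a4, an organic anion importer (-1.02 ± 0.14), fell. In all 383 genes changed (3.33%), 183 higher and 200 lower, 9 of them at least 2-fold. The largest rises were Tmem14a (1.13 ± 0.24), Il1r2 (1.13 ± 0.13), the dim gene Bcl2l12 (1.02 ± 0.27), Eno2 (0.84 ± 0.17) and Cyp1a2. The largest falls were the dim gene Ska3 (-1.67 ± 0.41), Sult1e1, Sult2a6 (-1.24 ± 0.20), Dhrs7l1 (-1.12 ± 0.14) and Omd (-1.05 ± 0.12). The call of Bcl2l12 was lost without 5 of 10 single arrays, and that of Ska3 in 2 of the 8 fits that kept the gene. Cyp7a1 (-0.98 ± 0.25, adjusted p = 0.0215), Slc10a1 (-0.49 ± 0.11, adjusted p = 0.0136), Abcb11 (-0.25 ± 0.04, adjusted p = 0.000411) and Pemt (-0.93 ± 0.11) fell. Cyp8b1, lower at 24 h, was at -0.22 ± 0.09 and did not pass (adjusted p = 0.224). The call of Cyp7a1 was lost without 5 of 10 single arrays, and that of Slc10a1 without replicate 5 of that dose.

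Of the preset list calls at 0.8 µM and 48 h, 17 in number, 5 held with an estimated correlation. They were AhR targets, with 3 of 6 higher (3 adjusted over the list alone; adjusted p = 0.00064 with an estimated correlation), and 4 lists with members lower. Of 15 fatty acid and triglyceride synthesis genes 7 fell (9 adjusted over the list alone; adjusted p = 0.0124 with an estimated correlation), such as Thrsp (-0.42 ± 0.08), while Fasn was at -0.48 ± 0.14 (adjusted p = 0.0574). The exact permutation did not call that list (adjusted p = 0.0612). Of 20 P450 and flavin monooxygenase genes 9 fell (13; adjusted p = 0.000699 with an estimated correlation), such as Cyp2c11 (-0.49 ± 0.09) and Cyp2d3 (-0.49 ± 0.08). Of 20 transporters 5 fell (6; adjusted p = 0.00149 with an estimated correlation), and of 9 gluconeogenesis genes 2, Pc (-0.49 ± 0.07) and Gys2 (-0.42 ± 0.06) (3; adjusted p = 0.0124 with an estimated correlation). The aminoacyl-tRNA synthetases, higher at 20 µM, had 2 of 12 members lower (3), Eprs1 (-0.27 ± 0.06) and Mars1 (-0.22 ± 0.06, lost without 8 of 10 single arrays), and their list call was lost (adjusted p = 0.0821 with an estimated correlation). Amino acid catabolism (adjusted p = 0.0698 with an estimated correlation) and cholesterol synthesis (adjusted p = 0.0821 with an estimated correlation) lost theirs as well. So did the integrated stress response, with 3 of 22 lower and 1 higher (6 and 1; adjusted p = 0.186 with an estimated correlation), where Asns fell (-0.31 ± 0.07, adjusted p = 0.013). Without replicate 3 or 5 of the dose group or replicate 4 of the vehicle group, 237, 199 and 228 genes were called, and median centring of the arrays gave 173.

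Set directly against 0.8 µM, the cells at 20 µM had higher transcripts of the integrated stress response and of aminoacyl-tRNA synthetases and lower transcripts of metabolic enzymes. At 24 h 1797 genes differed, 999 higher and 798 lower at 20 µM (1249 and 449 with the arrays centred on their medians), and at 48 h 3097, 1673 higher and 1424 lower. At 48 h Trib3 was higher at 20 µM than at 0.8 µM by 1.21 ± 0.11 and Asns by 0.90 ± 0.07, of which 0.59 was a rise over vehicle at 20 µM and 0.31 a fall below vehicle at 0.8 µM, and Cyp7a1 was lower (-1.79 ± 0.25, adjusted p = 8.78e-07). Nqo1 was higher by 0.68 ± 0.05 at 24 h and 0.64 ± 0.05 at 48 h. Cyp1a1 differed by 0.26 ± 0.09 at 24 h (adjusted p = 0.0499, lost without 7 of 10 single arrays), and at 48 h by 0.18 ± 0.09, which did not pass (adjusted p = 0.163). The largest differences at 24 h included Cpeb1 (2.72 ± 0.67, dim), Rragd (1.44 ± 0.12), Acsm3 (-1.53 ± 0.17) and Bbox1 (-1.53 ± 0.14). At 48 h they included Sfn (2.26 ± 0.11), Tsx (2.16 ± 0.18), Cyp4a1 (-2.57 ± 0.15) and Ces1d (-2.56 ± 0.16). Of 22 integrated stress response targets, 14 were higher and 0 lower at 24 h (15 and 0 adjusted over the list alone; adjusted p = 0.0067 with an estimated correlation), and 18 higher and 1 lower at 48 h (18 and 2; adjusted p = 0.01 with an estimated correlation). With an estimated correlation 13 of 17 list calls held at 24 h and 12 of 19 at 48 h. Of 12 aminoacyl-tRNA synthetases, 8 were higher at 24 h (11; adjusted p = 0.0067 with an estimated correlation) and 11 at 48 h (12; adjusted p = 0.0082 with an estimated correlation).

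Changes at 0.8 µM and at 20 µM were set against the same vehicle arrays, which alone makes them correlate. Across genes the correlation was 0.522 at 24 h and 0.539 at 48 h, and unchanged groups simulated against shared vehicles gave 0.501 and 0.496. The covariance exceeded the simulated one by 0.0146 and 0.0326. With the vehicle arrays split between the comparisons, r was 0.132 and 0.238 (means of 20 splits). Both doses shared 44 higher genes at 24 h (6.15 from independent lists) and 40 lower (5.12), and at 48 h 161 higher (37.2) and 178 lower (29.8), and neither excess is an estimate of a shared effect.

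Loss of P450 and transporter transcripts at 20 µM was deeper at 48 h than at 24 h, and the rise of lysosomal transcripts was larger. The 20 µM effect differed between the times for 484 genes, 205 of them more positive and 279 more negative at 48 h. Cyp2e1 differed by -1.78 ± 0.13, Sult1e1 by -2.01 ± 0.23, Slc10a1 by -1.18 ± 0.16, Otc by -1.95 ± 0.35 and Cd68 by 1.34 ± 0.18. Ddit3 differed by 0.73 ± 0.17 (adjusted p = 0.00888), and Trib3 by 0.09 ± 0.16 (adjusted p = 0.851). With an estimated correlation 5 lists differed: P450 and flavin monooxygenase enzymes, with 9 of 20 lower (12 adjusted over the list alone; adjusted p = 0.000173 with an estimated correlation), transporters, with 5 of 20 lower (8; adjusted p = 0.000173 with an estimated correlation), CAR and PXR targets, with 1 of 13 lower, Cyp3a18 (4 lower and 1 higher; adjusted p = 0.00744 with an estimated correlation), fatty acid oxidation, with 7 of 17 lower (9; adjusted p = 0.0251 with an estimated correlation), and lysosomal proteins, with 4 of 29 higher (10; adjusted p = 0.0292 with an estimated correlation). Cholesterol synthesis enzymes had 5 of 17 lower (8), among them Ebp (-0.41 ± 0.08), and their call was lost (adjusted p = 0.0536 with an estimated correlation). The aminoacyl-tRNA synthetases (camera adjusted p = 0.314), NRF2 targets (camera adjusted p = 0.591) and the proteasome (camera adjusted p = 0.638) did not pass, so their calls at 24 h alone were not shown to differ from 48 h. With the arrays centred on their medians 251 genes differed.

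Vehicle cultures changed with time as well, which is the background for the comparisons at 48 h. Some markers of Kupffer cells and some interferon-stimulated genes fell, and some fatty acid oxidation genes rose, though the calls of these lists were lost with an estimated correlation. Clec4f, a Kupffer cell receptor (-1.26 ± 0.21), Isg15, an interferon-induced ubiquitin-like protein (-1.23 ± 0.23), and Cyp2c13 (-2.23 ± 0.25) fell, and Cd36, a fatty acid carrier, rose by 2.04 ± 0.18. In all 1516 genes differed between 48 and 24 h, 745 higher and 771 lower. The largest rises after Cd36 were Tsx (1.78 ± 0.18), Clec14a (1.65 ± 0.18), Serpine2 (1.44 ± 0.16) and Sult2a6 (1.43 ± 0.20), and the largest falls were Serpina6 (-2.89 ± 0.25), Car3 (-2.46 ± 0.33), Serpina3c (-2.37 ± 0.18), Cyp2c13 and Gstp3 (-2.07 ± 0.36). Of 13 interferon-stimulated genes 7 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.308 with an estimated correlation). Of 14 Kupffer cell and leukocyte markers 5 fell (6; adjusted p = 0.273 with an estimated correlation), and of 17 fatty acid oxidation genes 6 rose and 1 fell (10 and 1; adjusted p = 0.308 with an estimated correlation). The preset test called 15 lists, and with an estimated correlation 0 held, the lowest adjusted p being 0.16. Cyp7a1 rose by 1.01 ± 0.25 over the same time in vehicle, so its fall at 20 µM and 48 h was measured from a higher level. Of 15 fatty acid and triglyceride synthesis genes 7 rose and 1 fell in vehicle (8 and 2; adjusted p = 0.326 with an estimated correlation), Fasn by 0.62 ± 0.14, and the list median of 0.23 stood beside the -0.25 of 0.8 µM against vehicle at 48 h, so that fall too was measured from a higher level.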

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

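Of the tests in this part, those on the share of hepatocytes, on RNA quality and on simulated split covariances were chosen after the result was seen, and the tests on share and quality took the place of tests on the markers of other cell types and on exact p-values, whose values are given with them.

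Transcripts of metabolic enzymes fell at 20 µM and 48 h: over 92 genes of 5 lists the median was -0.66, with 74 lower. On scaled arrays, a smaller share of hepatocytes or an equal loss of their transcripts would have moved secreted proteins and transcription factors as much. Their median was -0.16, higher by 0.498 (SE 0.135, from resampling genes, which are not independent replicates). These values argue against such a cause for the whole fall, and one as small as -0.16 stays open. That list holds very bright transcripts such as Alb, and whether bright signals respond less was not tested. The markers of other cell types (median -0.04 ± 0.09, SE from resampling genes, and 0.16 for the 4 of 42 above the median signal) went both ways and decided nothing. RNA quality would have raised the ratios of 3' to 5' signal, but the upper bound of their log2 difference was 0.119, with exact p = 0.738 for Gapdh and 0.794 for beta-actin. Quantile normalization and median centring moved the median change of all genes at 48 h by only 0.0028 and 0.041. Under the scaling that moved them most, the 74 genes, chosen because they fell, kept a median of -0.89, against -0.93. The choice among these scalings thus did not make the fall. With shifts so small the test could hardly come out otherwise, and it cannot show a change common to all genes. Whether the loss was regulated was not tested, and a loss of particular hepatocytes of the lobule stays open.

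Changes at 20 µM and 48 h opposed the changes of vehicle over time: of 935 genes called in both, 687 went opposite ways (268 from independent lists). Both comparisons use the 48 h vehicle arrays, which alone gives an r of -0.509 in simulated groups, against -0.349 measured. The covariance was -0.0455, below the lowest of 100 simulated values (-0.0434), and with the vehicle arrays split r stayed between -0.163 and -0.0756 (0 of 100 simulated sets had a mean split covariance as low). The shared arrays therefore do not account for all of it, and what else does was not tested. At 0.8 µM the covariance of -0.0322 lay within the simulated range (lowest -0.0413), and with the vehicle arrays split r was negative in all 20 splits (-0.130 to -0.00795) with a mean covariance that 18 of 100 simulated sets reached, so whether the shared arrays account for all of it cannot be told.

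Aminoacyl-tRNA synthetases were called lower at 0.8 µM and 48 h by the preset test (median -0.14, with 2 of 12 members lower) and higher at 20 µM (0.24), and both calls were lost with an estimated correlation (adjusted p = 0.0821 and 0.12), that at 0.8 µM also under the exact permutation (0.0714). Without each of the 10 arrays in turn the largest camera adjusted p at 0.8 µM was 0.00214, so no single array decided it, though the range over all its alternatives was 2.77e-05 to 0.0821. The list mean was lower at 0.8 µM than in vehicle in 5 of 5 sets of arrays with consecutive numbers, so the fall did not come from a single set handled together. Each set held an array of every group in the same order. Position within a set therefore cannot be told apart from dose and time. Against the vehicle arrays at 24 h the median was -0.0666, between the bounds set for it, so high vehicle arrays at 48 h cannot be told apart from an effect of 0.8 µM.

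Other splits of the same arrays (100 per comparison, the real one included) called fewer genes than the real split except in 1 case. Every other split of the arrays of 2 groups keeps part of any real difference between them, as 5 arrays cannot be divided evenly. The counts of other splits can therefore lie above those of unchanged groups and are not a rate by chance. For the difference of the 20 µM effects, the residuals of a fit of dose and time were permuted over the arrays in place of splits, and are counted with them. The real count, the highest other and the number of splits with as many were 2738, 762 and 1 for 20 µM at 24 h, 4050, 1470 and 1 at 48 h, 95, 104 and 2 for 0.8 µM at 24 h, and 383, 13 and 1 at 48 h. They were 1797, 374 and 1 for 20 against 0.8 µM at 24 h, 3097, 810 and 1 at 48 h, 484, 2 and 1 for the difference of the 20 µM effects, and 1516, 512 and 1 for vehicle over time. Fewer than 5 of 100 splits reached each of these counts of genes, and except for 0.8 µM at 24 h only the real one did. For 0.8 µM at 24 h another split called more genes, 104 against 95. That count also moved between 16 and 147 without single arrays, so chance was not excluded for it. For the number of lists called with the preset correlation the values were 22, 22 and 4 for 20 µM at 24 h, 17, 20 and 4 for 0.8 µM at 48 h, 19, 20 and 4 for 20 against 0.8 µM at 48 h, and 15, 14 and 1 for vehicle. Fewer than 5 of 100 splits reached each of these counts. Other splits still called as many lists or more, except for vehicle, where 0 lists held with an estimated correlation. These counts alone therefore do not exclude chance for the lists. The values for lists were 20, 23 and 13 for 20 µM at 48 h, 12, 14 and 7 for 0.8 µM at 24 h, 17, 21 and 13 for 20 against 0.8 µM at 24 h, and 13, 19 and 5 for the difference of the effects, where 5 or more reached the count and chance was not excluded.

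The 20 µM effect differed between the times by the interaction term for 484 genes, and the genes named by rule were Cyp2c11 (-1.46), Slc10a1 (-1.18), Ddit3 (0.73), Pdk4 (-0.96), Cyp7a1 (-1.27), Ces1d (-2.26) and the dim genes Lama5 (2.64), S100a1 (2.40), Ankrd63 (2.13), Rbm11 (2.03), Bank1 (2.02), Cyp2c12 (-2.52), Pdzk1ip1 (-2.47), Olr59 (-2.16) and Dhrs7l1 (-2.02). Leaving out single arrays ended the calls of Lama5 and S100a1 (16 of 20 arrays each), Ankrd63 and Pdzk1ip1 (14 each), Rbm11 and Bank1 (11 each) and Cyp7a1 (9), and Cyp2c12 was at -1.84 without replicate 4 of 20 µM at 48 h. The lists that differed had medians of -0.30 for fatty acid oxidation, 0.17 for lysosomal proteins, -0.24 for CAR and PXR targets, -0.40 for P450 and flavin monooxygenase enzymes and -0.18 for transporters.

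Single arrays stood far from the others of their group by Dixon's ratio of gap to range (limit 0.71), which chance gives in about 1 in 20 groups: 1 of 48 groups for array measures (2.4 by chance), 9 of 120 for panel genes (6 by chance) and 9 of 76 for the largest changes (3.8 by chance). At 0.8 µM and 24 h replicate 1 stood apart for the first principal component (0.721), Hmox1 (0.778), Fasn (0.796) and Cyp7a1 (0.924). In vehicle at 24 h replicate 5 did for Abcb11 (0.754), Cyp7a1 (0.737) and Bbox1 (0.821), and in vehicle at 48 h replicate 4 for Cyp8b1 (0.824) and replicate 5 for Olr59 (0.743). At 20 µM and 24 h replicate 5 did for Hspa5 (0.731) and Pfkfb4 (0.909) and replicate 2 for Pla2g4b (0.727). At 20 µM and 48 h replicate 5 did for Cdkn1a (0.775), Eno2 (0.732), Il1r2 (0.753) and Otc (0.877) and replicate 4 for Sult2a6 (0.875) and Cyp2c12 (0.819), and at 0.8 µM and 48 h replicate 4 for Ddit3 (0.788).

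Of 5550 kept probe sets without a single gene name, 602 changed at 20 µM and 24 h (10.9%, against 19.7% of named ones) and 996 at 48 h (17.9%, against 30.0%).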

How the results depend on the processing

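Of the alternatives, the exact permutation of list means was chosen after the data were seen, and where no cause is named the cause was not tested. No call of a named gene or of a list changed direction under any alternative in which such calls were followed. For the summary of probe sets and the threshold only the numbers of changed genes were taken, so named genes and lists were not followed there. Leaving out 1 array in turn gave 2437 to 2668 genes for 20 µM at 24 h, 3726 to 3864 at 48 h, 1489 to 1759 and 2793 to 2935 for 20 against 0.8 µM, 371 to 647 for the difference of the 20 µM effects, 1227 to 1685 for vehicle over time, 16 to 147 for 0.8 µM at 24 h and 199 to 384 at 48 h. For 0.8 µM at 24 h the count was 147, 21, 16, 34 and 38 without replicates 1 to 5 of that dose and 62, 16 and 46 without vehicle replicates 2, 4 and 5, and at 48 h it was 237 and 199 without replicates 3 and 5 and 228 without vehicle replicate 4. Median centring gave 12 (0.8 µM, 24 h), 173 (48 h) and 251 genes (difference of effects), and raised the share of higher genes at 20 µM and 24 h to 69.1%. For 0.8 µM at 24 h, eBayes without trend gave 52 genes, a fit of the compared groups 7 and all probe sets 60. Stricter thresholds call fewer genes by construction: an adjusted p under 0.01 gave 11 and 126 (0.8 µM), 1074 (20 against 0.8 µM, 24 h), 208 (difference of effects) and 850 (vehicle), and at least 2-fold gave 109 and 373 (20 µM), 4 and 9 (0.8 µM), 47 and 190 (20 against 0.8 µM), 48 and 66. With an estimated correlation camera called 13 and 10 lists (20 µM), 4 and 5 (0.8 µM), 12 (20 against 0.8 µM, 48 h), 5 (difference of effects) and 0 (vehicle, where the preset correlation called 15), and at 0.8 µM and 24 h fry called 6 and the exact permutation 0. Elsewhere the exact permutation called 24 and 26 lists (20 µM), 12 (0.8 µM, 48 h), 20 and 24 (20 against 0.8 µM) and 12 (vehicle). Counted at each time, it called 9 lists at 20 µM that camera did not, and fry 13, among them CAR and PXR targets, autophagy and cell cycle at 48 h (0.0119 each by permutation), and both ask whether a list moved at all, not whether it moved more than other genes. The agreement of 20 µM effects across time was 0.421 without a filter and 0.760 with the 60th percentile, and that of the doses 0.132 and 0.238 with the vehicle arrays split. Uncalled results changed sign: phospholipid synthesis (adjusted p = 0.973) and cholangiocyte markers (0.845) at 20 µM and 24 h with the 60th percentile, heat shock (0.973) and endothelial lists (0.741) at 48 h with fry, and with the exact permutation fatty acid synthesis (0.667) and heat shock (0.857) at 24 h and acute phase (0.918), interferon (0.411) and endothelial lists (0.947) at 48 h. So did Ddit3 (-0.0083), Fasn (-0.0057) and, at 48 h, Alb (0.0047) at 0.8 µM with quantile normalization, Ddit3 (-0.0010) with median centring and Fasn (-0.0087) with array weights. Leaving out arrays gave ranges across 0 for Trib3 (-0.0859 to 0.0344), Ddit3 (-0.0778 to 0.0988), Fasn (-0.1316 to 0.1211) and Cyp3a9 (-0.0175 to 0.2206) at 0.8 µM and 24 h, and Alb (-0.1318 to 0.0157) and Cdkn1a (-0.0148 to 0.0842) at 20 µM and 48 h, and changed the sign of phospholipid synthesis at 24 h (0.648 to 0.995) and of endothelial markers at 48 h (0.689 to 0.980). Of calls of named genes, 84.6% held under median centring, 92.9% without trend and 90.1% over the leave-one-out fits. Dim signals limit the genes named dim.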
